A study of Mus musculus with 64 samples.

How the data were processed

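The data are single-cell RNA-seq counts from 64 cells of mouse teeth, 32 sorted from molars and 32 from incisors. Per the labels' protocols, the teeth came from XLacZ4 mice, a line that carries a lacZ reporter, and were dissociated into single cells. The cells were stained with FDG, a substrate that becomes fluorescent when cut by beta-galactosidase, and the positive cells were isolated by fluorescence-activated sorting. The labels call all 64 cells pericytes. Libraries of polyA RNA were made with Smart-Seq2, a full-length protocol without molecular identifiers, so a count is a read and several reads can come from 1 molecule.

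The deposited values are raw whole-number read counts per gene symbol and cell, as the authors left them, with no scaling. Trim Galore, HISAT2 (2), Seurat (3) and the mm10 genome build are named per the submitters' processing notes. The counting tool, the gene annotation and any filter on cells are not given in the sources used here. Of the 188 columns of the count table, 64 match a labelled cell by name, and the other 124 match none and were not used here. The table has 24530 gene symbols, of which 14282 have at least 1 count in the 64 cells. 23784 symbols match the GENCODE M21 gene names. Another 24 symbols read as dates, as spreadsheet programs make of some gene names, and were left as they are; they hold 0.176% of the counts. Of the genes in the lists below, 16 have no entry under their symbol, among them all 13 mitochondrially encoded genes, so no share of mitochondrial RNA was computed. Gene positions are from GENCODE M21 on GRCm38, the same assembly as mm10, matched by symbol.

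Total counts per cell ran from 514492 to 3171734, and genes with a count from 922 to 4213. All 64 cells passed the filter of at least 10000 counts and 500 genes. The highest correlation between any 2 cells was 0.511, so no cell was entered more than once. The labels name 0 animals, so each tissue counts as 1 sample and the cells are not replicates. No test between tissues was made, no p-value is given, and differences have no replicate check. Counts were summed over the cells of a tissue and given as CPM (counts in each 10 to the power of 6 library counts), with exact Poisson intervals. Shares of cells have exact Clopper-Pearson intervals. All intervals are at the 95% level and, like the limits given for counts of 0, cover counting error only. The intervals on counts treat reads as independent. PCR reads without molecular identifiers are not independent molecules, so these intervals are too narrow for molecules and leave out the spread between cells. A count of 0 was replaced by a limit of 3 counts over the group when a fold was computed. A fold given as at least some value thus bounds the summed counts of these cells, not a difference between tissues. The limit given beside a share of 0 is likewise 3 cells of the total, which can differ from the exact interval, and it limits cells with a read, not cells that express the gene.

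Log2 ratios of molar over incisor were taken on summed CPM with a pseudocount of 1 CPM. For shares of cells with a read, each cell was thinned to 1040000 reads, the 10th percentile of the totals rounded down to a multiple of 10000, which left out 1 molar and 6 incisor cells and kept 31 and 26. Genes were named by a rule of size set before the data were examined: at least 20 CPM in 1 tissue, an absolute log2 ratio of at least 1, and a share of thinned cells differing the same way by at least 20 percentage points. The 12 genes with the largest share difference were taken in each direction over all cells, and the 8 in each direction within mural-like cells. Predicted genes were not named. In addition, 8 fixed genes (Rgs5, Pdgfrb, Cspg4, Acta2, Pecam1, Col1a1, Ptprc and Glb1), all members of the odontogenic homeobox and sex-linked lists, and up to 3 members with the most counts of each list described are named. Some genes that meet these rules are not reported here.

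There were 44 gene lists, 20 of cell type markers and 24 of pathways and other groups, all set before the data were examined. A list was measured where at least 3 members had a mean of at least 5 CPM over both tissues. Its median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 10 bins, and a list outside percentiles 2.5 to 97.5 is said to lie outside the central 95% of random lists. This describes these libraries and is not a test.

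Cells were clustered with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 on log-transformed counts scaled to 10000 per cell, with the 1000 most variable genes, 10 principal components and 10 nearest neighbours. Clusters were named from the fixed marker lists alone. No doublet caller was run, because the cells were sorted 1 at a time and number 64; a cell holding markers of 2 types is weighed in the closing section. The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used matplotlib 3.10.9.

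The calculations were tested on simulated counts for molar and incisor cells, drawn from the mean levels of the 14282 genes with a gamma spread between cells, with 200 genes made 4 times higher or lower. The median log2 ratio of these genes was 1.94 and -2.01, and 94% and 97% of them passed the limit of 1. Of 400 random lists without change, 6.25% lay outside the central 95%, and a list of 15 raised genes lay at percentile 100. These simulated cells had no cell types, their genes varied independently, and only the comparison over all cells was simulated. The spread between cells was a fixed setting, not fitted to these data. The rule on shares of cells was not run on the simulated counts, and unchanged genes that pass the naming rule were not counted. The rates therefore do not cover the naming of genes in these data. Nor do they cover lists of genes expressed together in few cells, or the comparison within mural-like cells.

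Alternatives set beforehand were the mean of per-cell CPM in place of sums, TMM scaling, pseudocounts of 0.1 and 5 CPM, no limit and a limit of 20 CPM on list members, no depth filter and a stricter one of 50000 counts and 1000 genes, sums without the deepest cell or without the cell with most counts of a gene, shares without thinning, at 520000 reads or with at least 5 reads, and clustering with 500 or 2000 genes, resolution 0.5 or 1.5, and 7 or 15 neighbours. Further alternatives were chosen after seeing the data: leaving out each cell in turn, leaving out molar cell 10, incisor cell 13, incisor cell 10 or incisor cell 2, Rn45s and Malat1 taken out of the library size, sums after thinning, and the 48 macrophage-marker cells alone.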

Results

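The transcriptomes of 64 FDG-positive single cells were compared between 2 kinds of mouse teeth, the molars, which are rooted and stop growing, and the incisors, which grow throughout life. The 32 molar cells held 514492 to 3171734 counts each (median 1770700) and the 32 incisor cells 604882 to 3106531 (median 1622060). The median number of genes with a count was 2520 in molar cells and 2801 in incisor cells. Summed over cells, the counts came to 61106898 for molar and 55880462 for incisor.

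The first question was which cell types the sorted cells resembled, since all of them are labelled pericytes, the contractile support cells on the outer wall of small vessels. Most cells of both tissues carried macrophage genes, and fewer than 1 in 4 fell in a group marked by pericyte genes. Clustering gave 3 groups of 26, 23 and 15 cells. The third cluster was mural-like, a name for pericytes and vascular smooth muscle cells together: on average 60.9% of its cells had a read of a pericyte marker and 1.21% of a macrophage marker. In the first and second clusters these values were 3.85% and 5.51% for pericyte markers against 80.4% and 86.2% for macrophage markers, and both were named haematopoietic-like. In the third cluster, detection averaged 34.4% for fibroblast markers, with 6 of 12 read in at least 50% of the cells, 29.4% for vascular smooth muscle markers, with 3 of 12, and 7.69% for endothelial markers. Pecam1, an adhesion molecule of endothelial cells, had a read in 1 of the 64 cells.

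Rgs5, a regulator of G protein signalling used as a pericyte marker (chromosome 1, 169655501 to 169695813, plus strand), had reads in 15 of 15 mural-like cells, with a median of 30147 CPM. Incisor cell 2 stood apart with 570.4 CPM of Rgs5, the fewest genes (922), 11.9% of counts from the ribosomal RNA gene Rn45s and 15.3% from the nuclear RNA gene Malat1, against mural-like medians of 0.548% and 1.27%. Pdgfrb, the receptor that draws pericytes to vessels, and the mitochondrial protein gene Ndufa4l2 were each read in 13 of these cells. The potassium channel genes Kcnj8 and Abcc9 and the receptor gene Notch3 were each read in 12, the smooth muscle actin gene Acta2 in 10 and Cspg4, which encodes the NG2 proteoglycan, in 8. Csf1r, the receptor for macrophage colony-stimulating factor, and C1qa, a complement component made by tissue macrophages, had 0 reads in the mural-like cells (0 of 15, which allows a share of cells with a read of up to 20%). Leading genes of the third cluster by fold were Rgs5, Serpine2, Maged2, Myl9, Atp1b2, S1pr3, Gm13889, Fn1, Serpinh1 and Cnn3. Those of the first cluster included Fuca2, Snx24, Gmip and Fermt3, and those of the second Gch1, Il1rn, Il1a and Ccl7.

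Of the 49 haematopoietic-like cells, 48 carried macrophage markers. All 48 had reads of Csf1r and C1qa, 47 of C1qb, C1qc, Tyrobp and Fcer1g, 45 of the mannose receptor gene Mrc1, and 44 of Ptprc, the pan-leukocyte antigen CD45 (chromosome 1, 138062861 to 138175708, minus strand). Rgs5 had a read in 6 of the 48 cells, with a median of 0 CPM. The other cell, molar cell 10, had 0 macrophage markers. In it, 39.4% of all counts came from Amelx, which encodes amelogenin, the main matrix protein of enamel (chromosome X, 169176114 to 169187200, minus strand).

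Macrophage-marker cells made up 22 of 32 molar cells (68.8%, interval 49.99 to 83.9%) and 26 of 32 incisor cells (81.3%, 63.6 to 92.8%). Mural-like cells made up 9 of 32 molar cells (28.1%, 13.7 to 46.7%) and 6 of 32 incisor cells (18.8%, 7.21 to 36.4%). The intervals overlap and cover cells of 1 sample per tissue, so they do not decide whether the tissues differ, and the sort on FDG fluorescence sets which cells could enter them. Every clustering setting kept the same mural-like cells, apart from the stricter depth filter, which left out incisor cell 2 and kept the other 14.

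**Figure D1:**
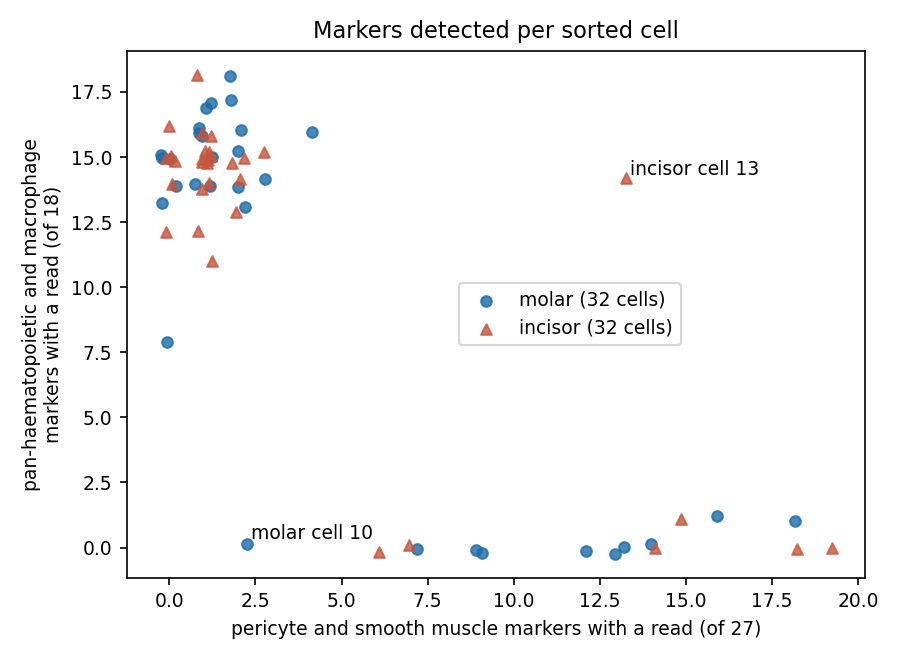
Each point is 1 sorted cell, with the number of pericyte and smooth muscle markers that have a read (of 27) on the horizontal axis and the number of pan-haematopoietic and macrophage markers with a read (of 18) on the vertical axis. Points are shifted slightly so that they do not hide each other, and cells of both tissues fall into 1 group at the upper left and 1 along the bottom while incisor cell 13 and molar cell 10 stand apart.

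Over all cells, the median share difference of all genes measured was -2.48 percentage points, which is toward incisor. The cells that thinning left out all carried macrophage markers. Mural-like cells were thus 9 of 31 molar and 6 of 26 incisor cells in the shares, against 9 and 6 of 32 in the sums. Higher in incisor by the largest share difference was Tmem87b, a gene for a Golgi membrane protein (chromosome 2, 128818118 to 128854261, plus strand). It stood at 264 CPM in incisor against 2.08 CPM in molar, a ratio of 127 (counting interval 107 to 152), with a read in 13 of 26 thinned incisor cells and 1 of 31 thinned molar cells. Fabp5, a fatty acid binding protein gene (chromosome 3, 10012548 to 10016607, plus strand), was 4.41-fold higher in incisor (201 against 45.5 CPM, 17 of 26 against 6 of 31 cells). Bre, a gene for a subunit of deubiquitinating complexes, had 51.5 CPM in incisor and 0 counts in molar, at least 1048-fold higher in incisor, with a read in 10 of 26 against 0 of 31 cells. Without molar cell 14 the ratio of Tmem87b was at least 5271, and without molar cell 22 that of Fabp5 was 11.2. Among the other genes higher in incisor, the amino acid transporter gene Slc43a2 was 6.22-fold higher. The ribosome biogenesis gene Nvl was 6.06-fold higher (4.02 without incisor cell 3, 11.2 without molar cell 5) and the nuclear pore gene Nup88 5.32-fold (233 without molar cell 19). Paics, of purine synthesis, was 3.92-fold higher (7.02 without molar cell 21, 7.12 without molar cell 28), and the ion channel gene Trpm7 3.53-fold. The lipid transfer gene Gltp was 3.07-fold higher (4.79 without molar cell 8), Cd300c2 2.66-fold (4.25 without molar cell 9) and the transcription elongation gene Paf1 2.19-fold.

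Higher in molar by the largest share difference was Atg16l2, a relative of an autophagy gene (chromosome 7, 101263034 to 101302251, minus strand). It stood at 103 CPM in molar against 2.77 CPM in incisor, a ratio of 37.2 (31.8 to 44.0), with a read in 14 of 31 thinned molar and 2 of 26 thinned incisor cells, and molar cell 32 gave 40.3% of its counts. The ratio was 22.8 without that cell and 59.7 without incisor cell 20. Map1lc3a, which encodes an autophagosome protein, was 3.92-fold higher in molar (206 against 52.6 CPM, or 8.02-fold without incisor cell 32). Bcap29, of the endoplasmic reticulum, was 28.5-fold higher (46.5 without incisor cell 7), and the transcription factor gene Creb1 8.22-fold (5.39 without molar cell 23, 63.3 without incisor cell 28). The corepressor gene Spen was 7.48-fold higher and the retinoic acid receptor gene Rara 6.69-fold (17.6 without incisor cell 32). The remaining 6 included Cul5 at 3.86-fold (6.11 without incisor cell 3), Galnt2 at 3.49-fold (7.63 without incisor cell 1) and Hivep1 at 2.61-fold (1.59 without molar cell 11, 7.35 without incisor cell 8). The last 3 were Sec62 at 2.24-fold, Tet3 at 2.09-fold (23.3 without incisor cell 14) and Arl5b at 2.03-fold (4.56 without incisor cell 1). The share intervals of the tissues overlapped for all of the 12 genes higher in molar but Atg16l2. They lay apart for 9 of the 12 genes higher in incisor, the direction in which the shares of all genes leaned. All of these genes were chosen by their share difference, so intervals that lie apart add no separate evidence. With each cell weighted equally, 3 of the 24 dropped below an absolute log2 ratio of 1: Tet3 at 0.38, Hivep1 at 0.94 and Paf1 at -0.83. In the macrophage-marker cells alone, 3 of them did so: Tet3 at 0.94, Paf1 at -0.82 and Gltp at -0.83.

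Among the 8 fixed genes, Rgs5 had reads in 13 of 31 thinned molar and 8 of 26 thinned incisor cells, Pdgfrb in 8 and 6, Cspg4 in 3 and 6, Acta2 in 14 and 13, and Ptprc in 20 and 20. Col1a1, the main chain of fibrillar collagen, had reads in 11 and 8, and Glb1, the cell's own lysosomal beta-galactosidase, in 4 and 4. Without thinning these were 13 and 8, 8 and 6, 3 and 6, 19 and 15, 20 and 25, 11 and 10, and 4 and 6 of 32 cells each. All of these pairs of shares had overlapping intervals. With at least 5 reads asked for, Acta2 was left in 12.9% of molar and 19.2% of incisor cells, from 45.2% and 50%.

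Gene groups were compared over the sums of all cells. Against a median log2 ratio of -0.13 over all 9934 genes measured, 7 of 32 measured lists lay outside the central 95% of matched random lists. The pericyte list had a median of 0.87 (percentile 99.9), with 8 of 14 members higher in molar and a mean of 0.16. In it, Rgs5 was 2.59-fold higher in molar (14467 against 5588 CPM), Ndufa4l2 4.10-fold and Kcnj8 2.06-fold (3.43 without incisor cell 24), whereas Cspg4 was 6.53-fold higher in incisor (97.2 against 14.9 CPM; 4.02 without incisor cell 22, 18.8 without molar cell 22). The vascular smooth muscle list had a median of 1.11 (percentile 98.4), with Acta2 2.20-fold (3.51 without incisor cell 28) and Myl9 1.70-fold higher in molar. Without molar cell 22 both were higher in incisor instead, Acta2 2.21-fold and Myl9 1.20-fold. The molar sum holds 9 mural-like cells, with 23694811 of its 61106898 counts, and the incisor sum 6, with 15018982 of 55880462. This difference in cell mix was not removed from the lists and folds over all cells. The pericyte, smooth muscle and matrix lists share it, so they are not separate results. Within the mural-like cells, the pericyte and smooth muscle medians were 0.38 and 0.60, inside the range of random lists. The fibrillar and basement membrane matrix list had a median of 0.50 (percentile 99.3), with 14 of 18 members higher in molar. Sparc, which binds collagen, was 1.70-fold higher and Col4a2, of basement membranes, 1.16-fold, and Col3a1 had 774 and 782 CPM (ratios without incisor cell 22 of 2.66 for Sparc and 2.55 for Col3a1). The list of matrix proteases and their inhibitors had a median of 0.60 (percentile 98.1), with the collagenase activator Mmp14 1.67-fold (2.62 without incisor cell 22) and Adamts1 1.52-fold (3.03 without incisor cell 28) higher in molar and the inhibitor Timp2 1.53-fold higher in incisor. Within the 48 macrophage-marker cells alone, the matrix and protease lists had medians of -0.57 and -0.20, and without incisor cell 13 the matrix list had 3.41. Within the mural-like cells the matrix list had a median of -0.06 (percentile 47.4) with a mean of 0.14, and 8 of 18 members higher in molar. Leaving out 1 cell ended the position outside the range for the pericyte list (0.40 without molar cell 15, 0.30 without molar cell 19, 0.39 without molar cell 31) and the matrix list (0.30 without molar cell 31). It did so too for the smooth muscle list (0.72 without molar cell 17), which turned to -0.47 without molar cell 22. The protease list moved inside for 10 of 64 cells, down to 0.42 without molar cell 4.

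The G2 and M phase list, of genes used in mitosis, had a median of -2.73 (percentile 0), with 16 of 16 measured members lower in molar. Cdc20, an activator of the anaphase-promoting complex, had 128 CPM in incisor and 0 counts in molar, at least 2616-fold higher in incisor (1203 without incisor cell 10, 1529 without incisor cell 26), and Mki67, a marker of cycling cells, was 4.21-fold higher (2.31 without incisor cell 26, 2.77 without incisor cell 5, 6.73 without molar cell 21, 9.69 without molar cell 18). Without incisor cell 10 the median was -1.44, inside the range. In the 48 macrophage-marker cells alone it was -1.14 (percentile 17.04), also inside, with 6 of 14 members higher in molar. In both tissues, 2 cells had reads of at least 10 of the 19 genes of this list, so the sums rest on few cells. The dental epithelium list had a median of 11.19 (13.30 with genes at 0 in incisor set at their limit), carried by molar cell 10, which held 99.8% of the counts of Amelx and of Ambn, another enamel matrix gene, and 100% of those of Enam. The endothelial list had a median of 2.41 over 4 members (percentile 98.4), among them Tie1 with 32.8 CPM in molar, all from molar cell 4. The median was 0.84 without that cell, 0.83 without molar cell 26 and 1.74 without molar cell 31, each inside the range.

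The other 25 measured lists lay inside the range of random lists, though some left it under other settings, as the closing section gives. The macrophage and monocyte list had a median of -0.01 and the pan-haematopoietic list one of 0.03. Tyrobp, a signalling adaptor of myeloid cells, stood at 1070 CPM in molar and 1051 in incisor, and Cd14, a lipopolysaccharide co-receptor, at 2576 and 2530.2 (a ratio of 1.58 without incisor cell 1). The lysosome list had a median of -0.42 (percentile 2.84), with 13 of 18 members higher in incisor, such as the protease genes Ctsb at 1.56-fold and Ctsd at 1.48-fold. The interferon response list had a median of -0.78 (percentile 4.33), although Irf1, a transcription factor gene of that response, was 1.67-fold higher in molar. The S phase list stood at -0.72 and the heat shock list at 0.37. Nuclear genes of oxidative phosphorylation had a median of -0.04, cytosolic ribosomal proteins -0.18, chromatin regulators -0.03, glycolysis 0.28, angiogenic signalling 0.27 and antigen presentation -0.45.

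**Figure D2:**
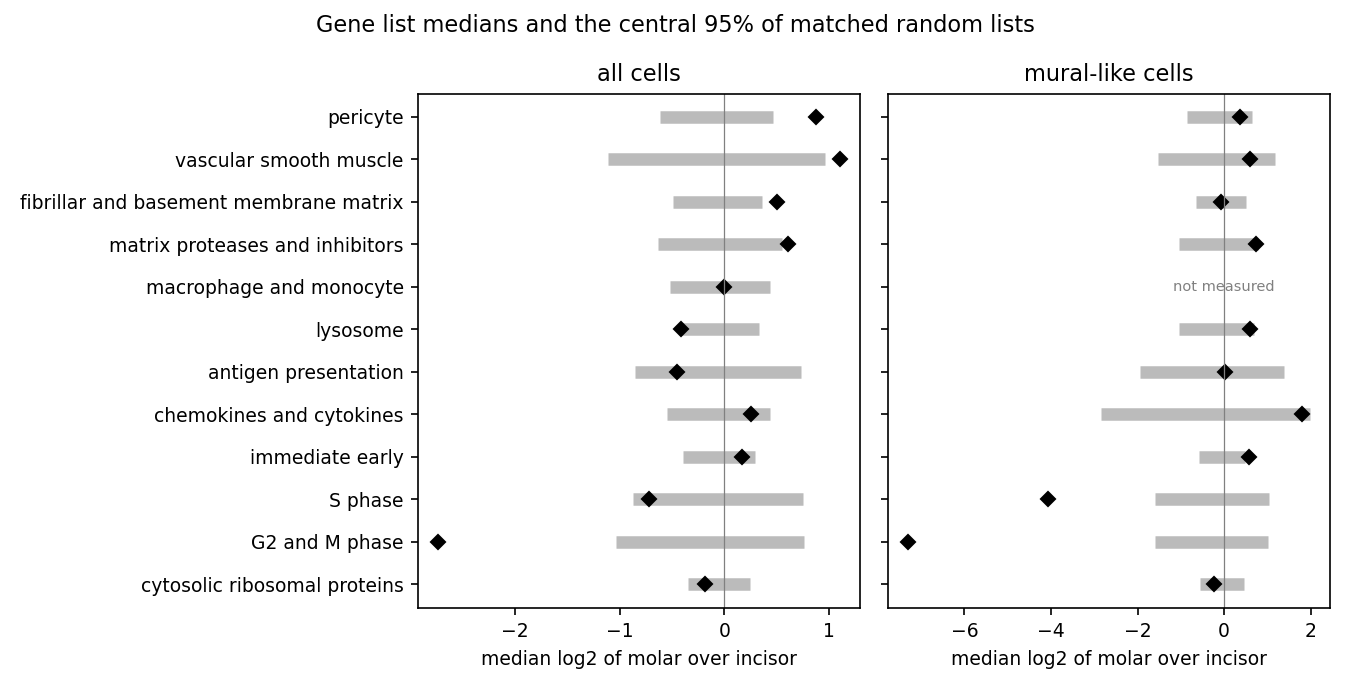
Diamonds give the median log2 ratio of molar over incisor summed CPM for 12 of the gene lists, over all cells on the left and over the 15 mural-like cells on the right, and grey bars give the central 95% of 10000 matched random lists. The G2 and M phase list lies to the left of its bar in both panels, at -2.73 and -7.31, and the pericyte list lies to the right of it over all cells only.

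The second question was how the pericytes of the 2 tooth types differ, taken here in the 9 molar and 6 incisor cells of the mural-like cluster, which held 23694811 and 15018982 counts. Barx1, known from the mesenchyme of developing molars (chromosome 13, 48662998 to 48666507, plus strand), had 297 CPM (interval 290 to 304) in the molar cells and 0 counts in the incisor cells, at least 1486-fold higher in molar. It had a read in 6 of 9 molar cells (66.7%, 29.9 to 92.5%) and in 0 of 6 incisor cells, which allows a share of up to 50%, and in 0 of the 48 macrophage-marker cells. Msx1, a homeobox gene needed for tooth development (chromosome 5, 37820485 to 37824583, minus strand), was 7.64-fold higher in incisor (282 against 36.9 CPM, interval of the ratio 7.11 to 8.23), with a read in 5 of 6 incisor and 5 of 9 molar cells, and 13.01-fold higher without molar cell 31. In molar cells 4 and 17, Msx1 had only 1 and 4 reads.

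Other members of the odontogenic homeobox list were read in few mural-like cells. Dlx5 had 209 CPM in molar and 98.9 CPM in incisor, from 3 and 2 cells (higher in incisor, 1.51-fold, without molar cell 17, and 7.04-fold higher in molar without incisor cell 24). Dlx1 had 28.2 and 14.4 CPM, from 4 and 2 cells (molar over incisor 1.15 without molar cell 19, 32.4 without incisor cell 2). Msx2 was 5.92-fold higher in incisor, from 2 cells against 1 (3.94 without incisor cell 22, 3.44 without incisor cell 32, at least 374 without molar cell 22). Pitx1 and Lhx6 were read in 1 molar cell each, and Dlx2, Dlx3, Dlx6, Lhx8 and Pax9 in 1 incisor cell each. Isl1 had 0 counts in these cells. The list as a whole had a median of -2.67, inside the range of random lists (percentile 9.37), with 4 of 10 measured members higher in molar.

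Igfbp3, which binds insulin-like growth factors in the extracellular space (chromosome 11, 7206086 to 7213923, minus strand), had 634 CPM in the molar cells and 0 counts in the incisor cells, at least 3175-fold higher in molar. Jak2, the kinase of cytokine receptors (chromosome 19, 29251828 to 29313080, plus strand), was at least 1344-fold higher in molar, with 269 CPM against 0 counts. Both were read in 6 of 9 molar and 0 of 6 incisor cells. Jak2 stood at only 1.28 CPM in molar cell 1 and 1.20 CPM in molar cell 23, against 320 CPM or more in the other molar cells with a read. The fold limits were 2062 for Igfbp3 without molar cell 23 and 882 for Jak2 without molar cell 17. Such limits hold for the summed reads of these cells and are not lower bounds on a difference between tissues. Among the other genes named as higher in molar, Mrvi1, a mediator of relaxation in smooth muscle, was 2.79-fold higher (409 against 147 CPM, 7 of 9 against 1 of 6 cells; at least 1639 without incisor cell 28). Arap2, Sys1, Tsnax and Atxn1 had 0 counts in incisor and were at least 873-fold, 791-fold, 716-fold and 188-fold higher in molar. The limits were 467 for Sys1 and 462 for Tsnax without molar cell 15 and 118 for Atxn1 without molar cell 13. Higher in incisor was Eif3b, of the translation initiation machinery (chromosome 5, 140419328 to 140443360, plus strand), at 445 against 90.6 CPM, a ratio of 4.91 (4.68 to 5.16), read in 6 of 6 incisor and 1 of 9 molar cells (2.89 without incisor cell 2, at least 3051 without molar cell 1). Mmadhc, of vitamin B12 metabolism (chromosome 2, 50279881 to 50296801, minus strand), stood at 284 CPM in incisor against 0.084 CPM in molar, from 2 counts, a ratio of 3360 with a counting interval of 929 to 27750.5. Without molar cell 19 it was at least 1987. Gabpa, a transcription factor gene, and Rnf146, a ubiquitin ligase gene, were at least 1275-fold and 1202-fold higher in incisor, each read in 5 of 6 against 0 of 9 cells. The chaperonin gene Tcp1 was 6.56-fold higher in incisor (27.3 without molar cell 17) and Syncrip 528-fold (at least 2106 without molar cell 4). Ing3 was higher 32.4-fold (16.8 without incisor cell 24, 2703 without molar cell 19) and Rragc 28.6-fold (at least 1184 without molar cell 13). In every one of these 16 genes a single cell gave 20.1 to 52.8% of the counts. The mural-like incisor cells had more genes with a count than the molar ones (median 3583 against 2317), and the median share difference of all genes was -5.56 points, toward incisor. The share intervals of the tissues overlapped for all 8 genes named as higher in molar and for 4 of the 8 higher in incisor. Here too the genes were chosen by their share difference, so intervals apart add no separate evidence.

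**Figure D3:**
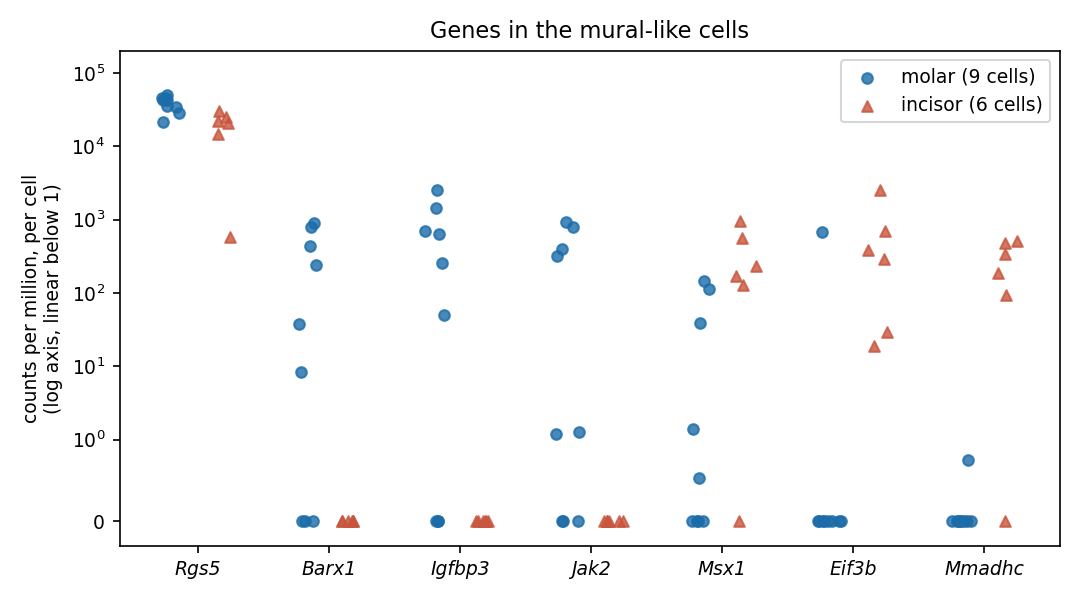
Each point is the CPM of 1 gene in 1 mural-like cell, on a vertical axis that is logarithmic above 1 CPM and linear below, with the 9 molar cells as circles and the 6 incisor cells as triangles. Rgs5 is present in all 15 cells, Barx1, Igfbp3 and Jak2 lie at 0 in the 6 incisor cells, and Mmadhc lies at 0 in 1 incisor cell and in all but 1 of the molar cells.

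As a group, pericyte markers in the mural-like cells lay inside the range of random lists. The pericyte list had a median of 0.38 (percentile 88.1) with a mean of -0.53, and the vascular smooth muscle list a median of 0.60 (percentile 87.5). Rgs5 was 1.82-fold higher in molar (37307 against 20541 CPM) and Pdgfrb 1.30-fold (878 against 676 CPM), but Pdgfrb was 1.23-fold higher in incisor without molar cell 31. Cspg4 was 7.29-fold higher in incisor (279.8 against 38.4 CPM, 5 of 6 against 3 of 9 cells; 4.16 without incisor cell 22, 19.2 without molar cell 22). Among signalling genes, the Notch ligand gene Jag1 was 6.09-fold and the Notch target gene Heyl 4.88-fold higher in incisor (10.7 and 8.37 without molar cell 31). Kitl, the ligand of the Kit receptor, was 5.04-fold higher in molar (3.34 without molar cell 23, 26.7 without incisor cell 32). The glycolytic enzyme gene Aldoa was 4.29-fold higher in molar, and Epas1, a factor of the response to low oxygen, 2.53-fold (4.45 without incisor cell 28). The Notch list had a median of 0.24 with a mean of -1.14, the BMP and TGF-beta list 0.60, the chemokine and cytokine list 1.81 (percentile 97.0) and the glycolysis list 0.34, all inside the range.

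In these cells 3 of 27 measured lists lay outside the range, against a median of -0.15 over all 7923 genes measured. The G2 and M phase list had a median of -7.31, or -10.04 with genes at 0 set at their limit, with 16 of 16 members lower in molar. Incisor cell 10 held reads of 18 of its 19 genes and gave 99.8% of the counts of Top2a, a topoisomerase gene. Without that cell the median was -5.00 and rested on incisor cell 32, with reads of 6 of the genes, since the other 4 incisor and all 9 molar cells had 0 or 1. The S phase list had a median of -4.06, or -5.53 with genes at their limit. It turned to 0.23 without incisor cell 32, which held reads of 14 of 16 S phase genes and gave 68.2% of the counts of Mcm6, of the replicative helicase. Mcm6 was 5.36-fold higher in incisor, 12.8-fold without molar cell 1, and 1.26-fold higher in molar without incisor cell 32. The immediate early list, of genes induced within minutes of stimulation or tissue dissociation, had a median of 0.59 (percentile 99.3), with 13 of 18 members higher in molar, such as Nr4a1 at 1.75-fold, while Fos was 1.37-fold higher in incisor (1.22-fold higher in molar without incisor cell 24). That list moved inside the range for 9 of the 15 cells left out in turn, with the lowest value, 0.29, without incisor cell 10.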

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

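Leaving out cells 1 at a time, the 48 macrophage-marker cells alone and the sums without the mural-like cell with most G2 and M genes were chosen after the data were seen, as was every alternative within those 48 cells; the others named here were planned unless stated. No paired analysis was possible because the numbers shared by molar and incisor cells only name cells, and the results come from no test between samples. Library sizes without mitochondrially encoded genes, and sums without cells rich in them, could not be run because the table has no such gene. TMM scaling moved the median log2 ratio of all genes over all cells by 0.13, from -0.13 to 0.00. Resolution 1.5 gave 5 clusters in place of 3. Over all cells, the vascular smooth muscle median was 0.97 with the mean of per-cell CPM and -0.48 without the deepest cell of each tissue, and the endothelial median was 1.38 with a pseudocount of 5 CPM and 0.52 with no filter on low members. In the macrophage-marker cells alone, the pericyte list turned to -3.78, the matrix list to -0.57 and the protease list to -0.20, and the G2 and M phase list was -1.14, inside the range of random lists. In mural-like cells, the S phase median turned to 0.13 without the deepest cell of each tissue, and the immediate early median was 0.29 without the cell with most G2 and M genes. In macrophage-marker cells, the chemokine and cytokine median was 0.49 with the mean of per-cell CPM. With each cell left out in turn, the medians over all cells ran from 0.30 to 1.30 for pericyte, -0.47 to 1.68 for smooth muscle, 0.83 to 3.18 for endothelial, 0.30 to 1.05 for matrix, 0.42 to 1.38 for protease and -3.31 to -1.44 for G2 and M phase lists. The dental epithelium list ran from 11.19 to 11.26 over 63 cells and could not be measured without molar cell 10. In mural-like cells the ranges were -6.26 to 0.23 for S phase, -7.62 to -5.00 for G2 and M phase and 0.29 to 0.74 for immediate early genes. In macrophage-marker cells they were 0.37 to 0.72 for chemokines and cytokines, and -4.43 to -3.78 for the pericyte list, which could not be measured without incisor cell 13. Lists inside the range of random lists moved outside it under some settings. Over all cells, the lysosome list did so with TMM (-0.30), the stricter depth filter (-0.45) and without the deepest cells (-0.49). The chemokine and cytokine list did so with the mean of per-cell CPM (0.57), members of at least 20 CPM (0.39) and macrophage-marker cells alone (0.54), the BMP and TGF-beta list with no filter on low members (0.49) and without the deepest cells (0.61), the interferon response list with no filter on low members (-0.78) and the immediate early list without the deepest cells (0.31). In mural-like cells, the protease list did so with the mean of per-cell CPM (0.95) and after thinning (0.95), and without the deepest cells the interferon response list (-4.66) and the chemokine and cytokine list (4.81). In macrophage-marker cells, the interferon response list did so without the deepest cells (-1.43), and the fibroblast and matrix lists without incisor cell 13 (3.41 each). The fibroblast and matrix lists share collagen genes, so their medians are not separate results. Sums after thinning and without incisor cell 13 were chosen after the data were seen. Of 16 shares of the fixed genes, 15 stayed within their intervals at 520000 reads and 14 with at least 5 reads; those outside were Acta2 in molar (25.8% and 12.9%) and in incisor cells (19.2% with at least 5 reads). The cause of these shifts was not tested.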

Other observations

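The comparison of macrophage-marker cells below, and the test of RNA from other cells in the first pattern, were chosen only after the result was seen. In the 22 molar and 26 incisor macrophage-marker cells, thinning left 21 and 20 cells. Ccl7, a chemokine that draws monocytes, was 2.53-fold higher in molar (16 of 21 against 7 of 20 cells; 6.01 without incisor cell 7). It is also a leading gene of the second cluster, which held 12 of the 22 molar and 11 of the 26 incisor cells, and this split was not removed. Igfbp4, which binds insulin-like growth factors, was 2.23-fold higher in molar (21 of 21 against 12 of 20 cells). Lpl, which releases fatty acids from lipoproteins, was 5.62-fold higher in incisor (12 of 20 against 2 of 21 cells; 3.50 without incisor cell 1, 25.5 without molar cell 30). The chemokine and cytokine list had a median log2 ratio of 0.54 (percentile 97.6) with a mean of 0.06, and lay inside the range of random lists for 26 of the 48 cells left out in turn. The pericyte list had a median of -3.78, carried by incisor cell 13.

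Both sexes were present in each tissue by sex-linked genes. Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254, minus strand), was read without Y-linked genes in 9 molar and 14 incisor cells, Y-linked genes without Xist in 15 and 13, both in 2 and 0, and neither in 6 and 5. With at least 10 reads asked for, 0 cells had both. In the macrophage-marker cells, Xist was read without Y-linked genes in 4 molar and 11 incisor cells. Y-linked genes were read without Xist in 13 and 12. These splits were not removed from the comparisons over all cells or from that of macrophage-marker cells above. Cells with many genes of the G2 and M phase list were macrophage-marker cells as well as mural-like ones: incisor cell 26 had reads of 17 of the 19 genes, molar cell 21 of 15 and molar cell 18 of 10, beside 18 in the mural-like incisor cell 10.

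Most cells labelled pericytes carried macrophage genes. RNA from other cells added to pericytes would have left Rgs5 near its mural-like level, yet its median in the 48 cells was 0% of the mural-like median (value 0). Rgs5 is among the markers that named the groups, so the grouping partly set this value and it does not decide alone. Over all 64 cells, without grouping, the median of Rgs5 was also 0 CPM, but this rests largely on the same 48 cells. It argues against added RNA as the source in most cells only if the pericytes sorted here carry Rgs5. The grouping cannot show that, since Rgs5 leads the mural-like cluster. Endogenous beta-galactosidase of macrophages read by the FDG stain could have brought them into the sort: Glb1 was read in 9 of 48 macrophage-marker cells (18.8%, 8.95 to 32.6%) and 1 of 15 mural-like cells (6.67%, 0.169 to 31.9%), a difference of 12.1 points with overlapping intervals, so the stain on Glb1 and the lacZ reporter cannot be told apart with these counts. The lysosome list as a whole was higher in macrophage-marker cells (median log2 1.85, 17 of 18 members, percentile 99.6). With no labelled FDG-negative cells to compare, this cannot show which enzyme the stain read, and that source stays open. Expression of the reporter in macrophages stays open too, and no biological explanation was tested.

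Amelx was read outside molar cell 10 in 9 of 31 other molar cells, with 1330 reads in all and 1 to 812 per cell, and in 0 of 32 incisor cells (up to 9.38%). If reads of that cell had been carried over in proportion, its 17 other genes with at least 1000 counts and no read in incisor cells would have given 180 reads in those cells, and 0 were found (observed over expected 0), which argues against carry-over of reads from that cell as a mixture of all its transcripts. Ambn came to 495 reads where 448 were expected, but 494 of them lay in molar cell 26, with 58 Amelx reads, and molar cell 32, with 812 Amelx reads, had 0 of 274 expected. Molar cells without Amelx had 582 reads of the 17 genes and 135 of Ambn, and Enam alone makes up 126 of the 180 expected reads. Single transcripts carried over before amplification stay open, as does expression in these cells or a difference between tissues, which was not tested.

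Incisor cell 13 carried both mural and macrophage markers. Genes typical of each class were chosen without this cell, as read in at least 60% of the cells of that class and at most 5% of the other. It had reads of 49% of 100 mural genes, where mural-like cells ran from 23 to 95%, and of 86.7% of 98 macrophage genes, where macrophage-marker cells ran from 39.8 to 91.8%. The lower of these shares was 2.13 times the lowest of its class, so 2 cells in 1 well may account for it. The median mural-like cell had 77% of the mural genes, so a limit set by the lowest cell is easily met. Rgs5 stood at 2301 CPM, 7.63% of the mural-like median. That lies within the 570.4 to 49583 CPM of single mural-like cells only through incisor cell 2, since the next lowest, incisor cell 10, had 14729 CPM. Of the mural-like cells, 2 had a share of mural genes at or under 49%. A single cell with both programmes stays open, and no biological explanation was tested.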
